A study of Mus musculus with 2 samples.

How the data were processed

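Mouse visceral adipose cells were measured in 2 single-cell libraries of polyA RNA made with 10x Genomics chemistry, 1 of old CD45+ cells and 1 of the adult stromal vascular fraction. The deposited values were whole-number UMI counts per gene and cell barcode, made with Cell Ranger and Seurat against mouse build mm10, per the submitters' processing notes. The tool versions and the gene annotation were not given in the sources used here. All steps below start from these counts, and the submitters' cell labels were not used here. Both matrices listed the same 28692 genes, and symbols carried by several gene IDs, 125 entries in all, were kept apart by ID. Coordinates came from GENCODE vM21 on GRCm38, in which all 370 genes looked up were found.

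The old library had 2986 barcodes with a median of 2823.5 UMIs, 1087 genes and 3.04% mitochondrial UMIs. The adult library had 5871 barcodes with a median of 2154 UMIs, 985 genes and 1.00% mitochondrial UMIs. Barcodes with under 200 genes (0 old, 4 adult) or 10% or more mitochondrial UMIs (19 old, 0 adult) were left out. Scrublet then marked 3 of 2967 old and 137 of 5867 adult cells as doublets, so few doublets can have been removed from the old library. The cells used numbered 2964 and 5730.

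Each library was clustered alone with scanpy 1.11.5 in Python 3.11.15 (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, matplotlib 3.10.9). Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used with random seed 0. Clusters named as T, NK or innate lymphoid cells were pooled and clustered again at the same settings, and their names begin with L. This gave 17 old and 18 adult clusters.

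Clusters were named from marker genes of 26 classes that were fixed before the data were examined, as were the gene lists, the rule for named genes, the comparisons and the first set of alternatives. A cluster took the class with the largest median log2 ratio of its markers over the lower quartile of the clusters, with 20 CPM added to each value. At least 3 markers, and more than 50% of those listed, had to exceed that lower quartile by more than 1 log2 unit. They also had to be present in at least 10% of the cells, and the median log2 ratio had to be at least 1. These naming settings were chosen after seeing the data. The leading genes of a cluster, also defined after seeing the data, were the 10 with the largest fold over cells of all other names, among genes with at least 20 UMIs. Class names are therefore given as "-like".

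UMIs were summed over the cells of a class and given as CPM. The 5 classes compared were ILC2-like, macrophage-like, T-cell-like, B-cell-like and NK- or ILC1-like cells, each with at least 30 cells in both libraries. Plasma-cell-like cells (145 old, 53 adult) and gamma delta T-like cells (84 old, 52 adult) also reached 30 but were not compared. Ratios are log2 of old over adult CPM with counts under 3 set to 3, with exact conditional binomial intervals at 95% computed from the counts. Shares carry Clopper-Pearson intervals, CPM values Poisson intervals, and a count of 0 an upper limit of 3 over the total. For each of the 25 gene lists, a class's median was taken over members with at least 10 UMIs in both libraries together. Its percentile among 10000 random lists of the same size, matched in 20 expression bins, describes these libraries only, and its interval comes from 1000 Poisson draws. The result of 1 list in macrophage-like cells is not reported here. Named genes were those with the largest ratios, 10 each way in ILC2-like and macrophage-like cells and 5 each way in other classes. They needed at least 20 UMIs in the higher library, a ratio of at least 2 and at least 25% of the CPM of the highest class there. Ribosomal, mitochondrial, haemoglobin, immunoglobulin, T cell receptor segment, sex-linked and predicted genes were left out of that rule.

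The ILC2-like sums held 176088 old and 85487 adult UMIs, and the macrophage-like sums 2952978 and 3182717. The T-cell-like sums held 2029148 and 278342, the B-cell-like sums 849023 and 166925, and the NK- or ILC1-like sums 383616 and 40941. The computation of the ratios was checked on simulated data with planted changes of 1 and 2 log2 units. The simulated sums were Poisson draws, which the intervals assume, so the check does not cover UMIs that gather in single cells. In ILC2-like cells 95% and 97% of 100 changed genes lay inside their interval, and in macrophage-like cells 96% and 98%. A list of 15 genes planted 1 log2 unit lower came out at percentile 0 in both, and unchanged lists at 38.0 and 43.9.

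The alternatives fixed beforehand were Leiden resolutions 0.5 and 2, clustering both libraries together, keeping predicted doublets, a filter of 500 genes and 5% mitochondrial UMIs, and cells thinned to 1000 UMIs. TMM factors from edgeR 4.0.16 in R 4.3.3, list members with at least 50 UMIs, members at class level only, and a gate on single cells were tried as well. The gate needed a UMI of Gata3, a UMI of Il1rl1, Il7r, Rora or Areg, and none of Cd3d, Cd3e, Cd3g, Cd79a, C1qa or Ncr1. TMM factors for ILC2-like cells were 0.993 in old and 1.01 in adult. Thinning left out 300 adult cells with fewer UMIs.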

Results

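Cells of mouse visceral adipose tissue (VAT) were profiled by droplet single-cell RNA sequencing in 2 libraries, 1 per group. The old library held tissue-resident cells carrying CD45, the surface protein of blood-derived cells. The adult library held the whole stromal vascular fraction (SVF), which is what remains of the tissue once the adipocytes are removed. Both came from wild-type C57BL/6 mice. The old library had 11950544 unique molecular identifiers (UMIs) in 2986 barcodes, with 1540 to 28667 per barcode. The adult library had 14525949 UMIs in 5871 barcodes, with 906 to 21318 per barcode. The series is about interleukin 33 (IL-33) and group 2 innate lymphoid cells (ILC2), lymphocytes without an antigen receptor, in aged fat. There were no replicates, so the intervals given are exact 95% intervals that cover counting error only. Age, cell fraction and sex of the animals all differed between the libraries, so no difference between them can be assigned to age.

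The first question was which cells carried Il33 and which carried its receptor. In the adult fraction Il33, which encodes an alarm cytokine held in the nucleus of barrier and stromal cells, was highest in mesothelial-like cells, the lining of the fat pad, at 105 CPM (the counts-per-million value of the class's summed UMIs, 92.5 to 120). It stood at 16.7 CPM (13.4 to 20.7) in stromal-progenitor-like cells, 8.83 in pericyte- or smooth-muscle-like cells and 6.02 in endothelial-like cells. The log2 ratio of mesothelial-like over stromal-progenitor-like cells was 2.66 (2.29 to 3.03). Mesothelial-like cells held 240 of the 343 Il33 UMIs of the stromal classes, or 70.0% (64.8 to 74.8). A UMI of Il33 was found in 30.5% of mesothelial-like cells at a median depth of 3583 UMIs, against 1.02% of macrophage-like cells at 2117. Among the stromal progenitors, cluster 9, whose leading gene was the adventitial marker Pi16, had 30.9 CPM of Il33 (23.5 to 39.9) and the other 3 clusters had 4.21 to 11.2. The old library, sorted for immune cells, held 1 UMI of Il33. The gene (ENSMUSG00000024810) lies on chromosome 19, from 29925114 to 29960718 in GRCm38.

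Other cytokine and chemokine genes of the stroma were spread over different classes of the adult fraction. Stromal-progenitor-like cells had the highest CPM among the stromal classes of the eosinophil attractant Ccl11 (1549), the neutrophil attractant Cxcl1 (1732) and the cytokine Il6 (233). Within that class Il6 reached 472 CPM (438 to 507) in cluster 7, of which it was a leading gene. Il7, a survival factor of lymphocytes, stood at 12.3 CPM (8.17 to 17.8) in mesothelial-like and 2.56 (1.36 to 4.37) in stromal-progenitor-like cells. Cxcl12, a retention signal for leukocytes, was at 782 CPM in endothelial-like and 677 in pericyte- or smooth-muscle-like cells, and Kitl, the ligand of the receptor Kit, at 164 and 137 CPM. Mfge8, which bridges dying cells to phagocytes, reached 657 CPM in pericyte- or smooth-muscle-like cells. No UMI of Il25, Nmu or Vip was found in stromal-progenitor-like cells, which allows up to 0.590 CPM of each.

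The receptor gene Il1rl1, which encodes ST2, marked both ILC2-like and Treg-like cells of the old library. It stood at 681 CPM (565 to 815) in ILC2-like and 844 CPM (773 to 921) in Treg-like cells. That cluster was named for regulatory T cells, and a UMI of Cd3d, Cd3e or Cd3g was found in 95.2% of its cells. Its 10 leading genes, however, held 4 ILC2 markers, Il1rl1 among them, and 3 Treg markers, and 38.1% of its cells had a Foxp3 UMI. All other classes were at or below 87.6 CPM, the value of cDC2-like dendritic cells. A UMI was found in 72.6% of ILC2-like cells at a median depth of 2157 UMIs and in 79.6% of Treg-like cells at 1975, against 5.53% of B-cell-like cells at 2653. ILC2-like cells held 120 of the 1102 Il1rl1 UMIs, or 10.9% (9.11 to 12.9), Treg-like cells 46.6% (43.7 to 49.6) and macrophage-like cells 18.1% (15.8 to 20.5). With every cell thinned to 1000 UMIs the ILC2-like share was 14.8%. Adult ILC2-like cells had 211 CPM (125 to 333) from 18 UMIs. Il1rl1 (ENSMUSG00000026069) lies on chromosome 1, from 40429570 to 40465415. The plot of Il33 and Il1rl1 by class shows both patterns.

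**Figure D1:**
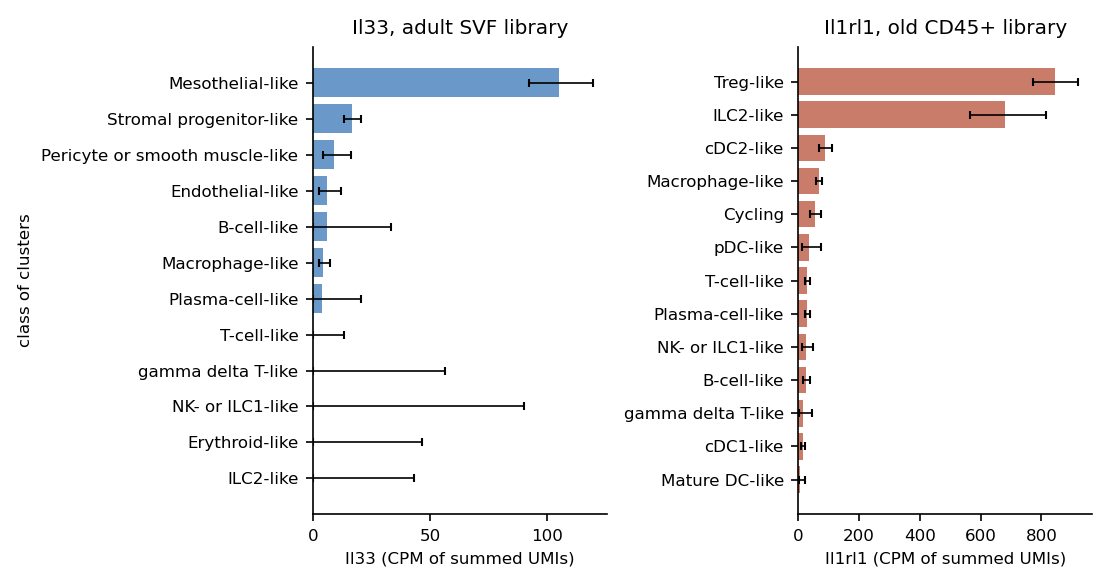
Bars give CPM of Il33 in the classes of the adult library and of Il1rl1 in those of the old library, and lines give exact 95% Poisson intervals, which cover counting error only. Il33 was highest in mesothelial-like cells at 105 CPM, and Il1rl1 in Treg-like and ILC2-like cells at 844 and 681 CPM.

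The next question was which immune cells each library held. Macrophage-like cells made up 19.5% (18.1 to 21.0) of the 2964 old immune cells and 74.9% (72.8 to 76.8) of the 1834 adult ones. Adult cluster 5 (355 cells) and old cluster 10 (179 cells) had no macrophage marker among their 10 leading genes. Their macrophage scores were 2.35 and 1.97, with cDC2 next at 1.51 and 1.65, so these shares may include dendritic cells. T-cell-like classes together made up 41.6% (39.8 to 43.4) in old and 12.0% (10.5 to 13.6) in adult. Without the Treg-like cluster, whose 10 leading genes held more ILC2 than Treg markers, the old share was 32.5%. A CD3 UMI was found in 95.2% of that cluster's cells, against 98.2% of T-cell-like and 65.8% of ILC2-like cells of the old library. B-cell-like cells were 8.54% (7.55 to 9.60) of old and 4.96% (4.01 to 6.06) of adult immune cells, and NK- or ILC1-like cells, which share natural killer genes, 5.74% and 1.96%. ILC2-like cells were 2.46% (1.94 to 3.09) of old and 3.33% (2.55 to 4.25) of adult immune cells. The order depended on the method. ILC2-like cells with no CD3 UMI kept it, at 0.843% (0.547 to 1.24) of old and 1.31% (0.840 to 1.94) of adult immune cells, with overlapping intervals. A CD3 UMI was also found in 41.1% of old and 11.0% of adult B-cell-like cells, so this filter can remove more old cells. The order turned in other settings. The adult share was 1.42% at Leiden resolution 2, 0.511% with both libraries clustered together and 0.436% in a gate on each cell. The old share there was 2.77%, 2.09% and 1.11%. Only 12 of the 33 gated old cells lay in the ILC2-like cluster, against 6 of 8 in adult. A gate on single UMIs also depends on depth, and ILC2-like cells had medians of 2157 UMIs in old and 1249 in adult. At resolution 0.5 no adult cluster was named ILC2-like, but adult cluster L2 of 63 cells, named T-cell-like, had the same score of 3.72 for both classes and 3 ILC2 markers against 1 T cell marker among its 10 leading genes.

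Several classes were found as clusters in the old library alone. Treg-like cells were 9.11% (8.10 to 10.2) of its immune cells, the 4 dendritic classes together 14.8% (13.6 to 16.2) and cycling cells 2.40% (1.88 to 3.01). No adult cluster had these names, which sets no limit on how many such cells were present. Markers of dendritic and cycling cells were found among adult immune cells. Cd209a stood at 178 CPM against 81.7 in old and the plasmacytoid marker Siglech at 28.9, from 118 UMIs in adult and 88 in the larger old total, while Clec9a (10.3 against 25.3), Xcr1 (5.87 against 28.7), Fscn1 (15.7 against 27.4) and the proliferation gene Mki67 (8.80 against 19.4) were lower. In the whole adult fraction, 1834 of the 5730 cells used were immune. Stromal-progenitor-like cells were 38.8%, endothelial-like cells 12.0%, mesothelial-like cells 10.1% and pericyte- or smooth-muscle-like cells 6.61%. The sort and the smaller number of immune cells in the adult library can set such shares.

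**Figure D2:**
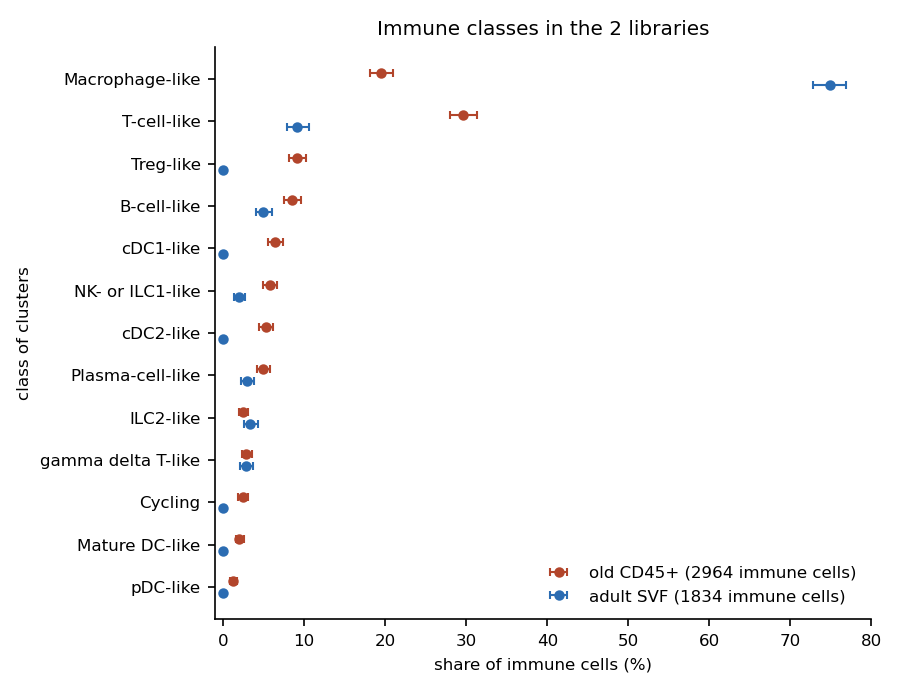
Points give each class as a percentage of the immune cells of its library, with exact 95% binomial intervals as lines, for the old CD45+ and the adult SVF library. Macrophage-like cells were 74.9% of adult and 19.5% of old immune cells, and classes at 0 in adult had no cluster there, which does not bound the number of such cells.

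ILC2-like cells of both libraries were then compared. The genes that define ILC2 went both ways, while Il5 and Il13 were lower in the old cluster. Of 16 measured surface and transcription factor genes, 5 were over 2 times higher in old cells and none was over 2 times higher in adult cells. Gata3, the transcription factor of type 2 lymphocytes, stood at 494 CPM in old and 468 in adult cells, with a log2 ratio of 0.08 (-0.48 to 0.66). Il1rl1 had a log2 ratio of 1.69 (0.97 to 2.50), Id2, needed by all innate lymphoid cells, 1.31 (0.76 to 1.89) and Il7r, the interleukin 7 receptor, 1.04 (0.24 to 1.93). Thy1 went the other way, at -0.68 (-1.15 to -0.20). The median of the list was 0.16, at percentile 80.1 of 10000 random lists matched on expression.

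Of 13 measured ILC2 effector genes, 7 were over 2 times higher in adult and 3 in old cells. The median log2 ratio was -1.04 (-1.31 to -0.23), at percentile 0.03 of the random lists. Il5, which drives eosinophils, was at 62.5 CPM in old and 257 CPM in adult cells, a log2 ratio of -2.04 (-3.23 to -0.94) from 11 and 22 UMIs. Il13, which acts on macrophages and epithelium, had 3 UMIs in old and 10 in adult cells, a log2 ratio of -2.78 (-5.28 to -0.82). The old Treg-like cluster, left out of this comparison, held 15 of the 23 old Il13 UMIs and 7 of the 31 old Il5 UMIs. Over all immune cells Il13 stood at 1.93 CPM (1.23 to 2.90) in old and 2.69 (1.34 to 4.81) in adult, and Il5 at 2.61 (1.77 to 3.70) and 8.56 (5.96 to 11.9). The chemokine Ccl1 was at -3.57 (-4.55 to -2.71), the protease Furin at -1.39 (-1.80 to -0.97) and Arg1, the enzyme arginase 1, at -1.04 (-1.90 to -0.18). The cytokine Lif was higher in old cells at 1.70 (0.55 to 3.10), and Csf2, which encodes GM-CSF, stood at 0.59 (-0.14 to 1.37). Areg, the repair factor amphiregulin, differed little at -0.18 (-0.54 to 0.19). Ccl1, Furin, Areg, Gata3, Klrg1 and Cxcr6 were among the 10 leading genes of the adult cluster. Csf2, Lif, Hes1 and Il1rl1 were among those of the old one. These genes also set each cluster apart from the other cells of its library, so their ratios are not independent of the clusters. Il5 (ENSMUSG00000036117) and Il13 (ENSMUSG00000020383) lie on chromosome 11, from 53720794 to 53725106 and from 53631324 to 53634702.

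**Figure D3:**
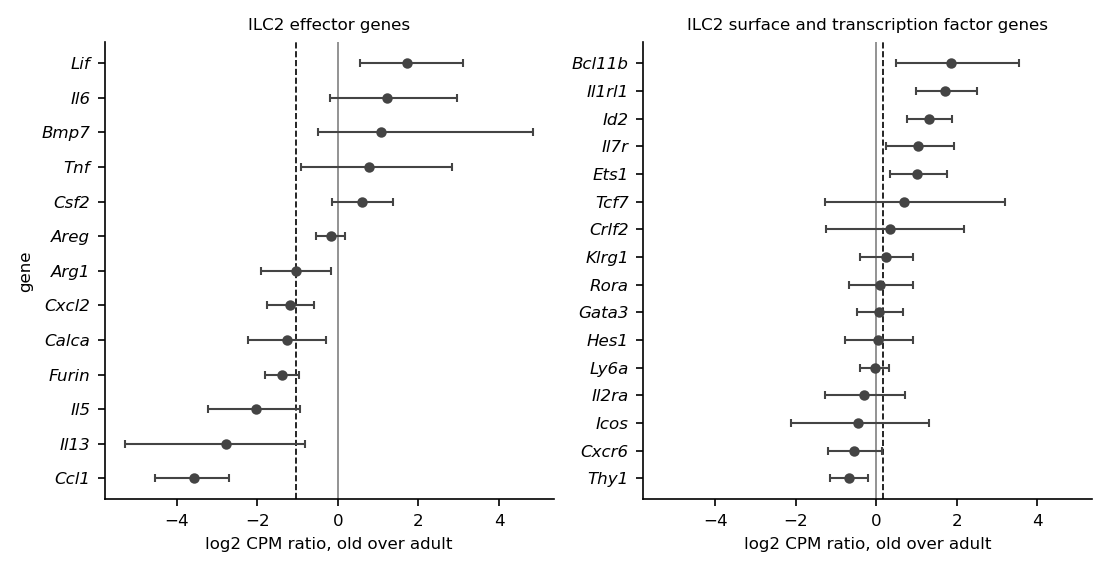
Points give the log2 ratio of CPM, old over adult, of each measured member of both ILC2 lists in ILC2-like cells, with exact 95% intervals for counting error as lines and each list's median as a dashed line. The effector median lies at -1.04 and the surface and transcription factor median at 0.16.

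Both ILC2-like clusters held cells with T cell transcripts. The adult cluster scored 3.79 for ILC2 and 3.64 for T cells, close to a tie, and the old cluster 3.32 and 1.68. The CD3 genes, which belong to the T cell receptor complex, summed to 892 CPM (758 to 1042) in old and 1521 CPM (1271 to 1806) in adult ILC2-like cells. In B-cell-like cells, which lack them, they stood at 216 and 89.9 CPM, and in T-cell-like cells at 2105 and 1775 CPM. A CD3 UMI was found in 48 of 73 old and 37 of 61 adult ILC2-like cells, with 65.8% and 60.7%, against 41.1% and 11.0% of B-cell-like cells. Median depths were 2157 and 1249 UMIs in ILC2-like and 2653 and 1451 in B-cell-like cells. Hes1 and Trac, chosen after their values were seen, split by CD3. Cells with no CD3 UMI held 39 of the 40 old and 18 of the 19 adult UMIs of the Notch target Hes1, and 1 of 28 old and 0 of 41 adult UMIs of the T cell receptor gene Trac. Among the 25 old and 24 adult cells with no CD3 UMI, the effector median was -0.44 (-1.10 to 0.40), an interval that includes 0. It was taken over 9 genes, Il13 not among them, against 13 genes in all ILC2-like cells, so the 2 medians differ in genes as well as cells. In these cells Il5 had 2 UMIs in old and 11 in adult, Il13 0 and 8, of which 4 were in a single adult cell, and Ccl1 a log2 ratio of -2.86 (-4.43 to -1.55). Areg was higher in the old ones, at 1.88 (1.08 to 2.78). That cell carried 347 UMIs of mast cell genes. Without it the effector median was -0.65 (-0.89 to -0.14), and -0.54 (-1.20 to 0.30) among cells with no CD3 UMI. All ILC2-like cells held 3 old and 10 adult UMIs of Il13, 4 of them in that cell. Without these 4, Il13 falls under the list minimum of 10 UMIs and leaves the list. The median of -0.65 therefore differs from that over 13 genes in its gene set as well as in its cells.

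The genes with the largest ratios in ILC2-like cells included few cytokines. Higher in old were Ubl3 at 2.84 (1.41 to 4.76) and Ikzf1, a lymphoid transcription factor, at 2.28 (0.96 to 3.96). Dusp2, Dcun1d5, Ndufc2 and Ptbp3 had 32 to 37 UMIs in old and 3 in adult cells, and Cd48, Hnrnph1, Klf3 and Ddx6 had 29 to 32 in old and 1 or 2 in adult. Higher in adult, beside Ccl1 and Il5, were the glycolytic enzyme gene Hk2 at -3.57 (-5.56 to -2.02), the interferon-induced Ifi27l2a at -2.20 (-2.78 to -1.64), Rgcc at -2.15 (-2.59 to -1.73) and the protease inhibitor Serpinb1a at -1.85 (-2.83 to -0.91). The mast cell genes Tpsb2, Cma1, Mcpt4 and Cpa3 had 124, 100, 94 and 30 UMIs in adult and 0 in old cells, nearly all in the cell named above.

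Other gene lists were measured in ILC2-like cells as well. The 6 measured inhibitory receptor and exhaustion genes had a median of 0.39 (percentile 72.5), with Maf at 1.66 (0.13 to 3.64). The 14 senescence and secretory genes stood at 0.25 (percentile 73.1), the 20 oxidative phosphorylation genes at 0.22 (percentile 89.8), the 8 interferon response genes at -0.35 (percentile 7.88) and the 17 dissociation and immediate early genes at -0.12 (percentile 32.7). The 6 MHC class II presentation genes had a median of 0.86 (percentile 99.6), and each stood below 25% of the highest class of its library, such as Cd74 at 1357 CPM in old and 831 in adult cells. RNA from other cells moved with the library. The 7 measured stromal free RNA genes had a median of -4.59, the 8 macrophage ones -1.80 and the 3 haemoglobin genes -2.16. The matrix gene Dcn had 63 UMIs in adult and 0 in old ILC2-like cells.

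Macrophage-like cells of the libraries differed in the genes of resident tissue macrophages. All 17 listed genes were higher in adult cells, 16 of them over 2 times, with a median log2 ratio of -4.85 (-5.49 to -4.76) at percentile 0 of the random lists. Folr2, a folate receptor, was at 10.8 CPM in old and 1119 in adult cells, a log2 ratio of -6.69 (-7.24 to -6.19). The haemoglobin scavenger receptor Cd163 was at -6.22 (-7.09 to -5.47), and Retnla, induced by type 2 cytokines, at 9853 and 18375 CPM. The hyaluronan receptor Lyve1 had 532 UMIs in adult and 0 in old cells, 165-fold lower with 3 counts as the floor. Timd4, a receptor for dying cells, had 255 and 0. Different clusters made up the class. Old cells were in cluster 15, led by C1qb, C1qa and Apoe, with 69.1% of the class, and cluster 10, led by Retnla, Lpl and Lyz1. Adult cells were in clusters 3 and 4, with 41.4% and 32.8%, which carried Lyve1 at 345 and 134 CPM, and in cluster 5, led by Lyz1, with 25.9% and 3.88 CPM of Lyve1. The monocyte chemokine receptor gene Ccr2 was at 1095 and 696 CPM in old clusters 15 and 10, and at 37.0 to 227 CPM in the adult ones.

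Genes of inflammation did not move as a group. The 19 inflammasome and NF-kB cytokine genes had a median of -0.09 (percentile 6.14), with 7 over 2 times higher in old and 5 in adult cells. Il1b stood at 1601 CPM in old and 348 in adult cells, a log2 ratio of 2.20 (2.11 to 2.30), Il6 at 2.75 (2.44 to 3.08) and Ptgs2, which makes prostaglandins, at 2.68 (2.24 to 3.15). The chemokines Ccl7 and Ccl2 were lower in old cells, at -3.63 (-3.75 to -3.51) and -1.74 (-1.82 to -1.66). The 18 lipid-associated macrophage genes had a median of 0.29 (0.01 to 0.41) at percentile 76.1, and 5 were over 2 times higher each way. Lpl, which releases fatty acids from lipoproteins, was at 2.33 (2.21 to 2.45) and the integrin gene Itgax at 2.22 (1.70 to 2.77), while Cd63 was at -2.22 (-2.38 to -2.06). The receptor Trem2 did not differ beyond counting error, at 0.02 (-0.24 to 0.27). This median was -0.20 with each cell thinned to 1000 UMIs and 0.58 in the C1q-high clusters alone. Fabp4, at -5.14, stood below 25% of the highest class of the adult library, as did Cd36.

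Maoa, which degrades noradrenaline, had 2 UMIs in old and 81 in adult macrophage-like cells. Gdf3, a growth factor gene, was higher in old ones, at 1.30 (0.59 to 2.06). The 22 interferon response genes had a median of -0.82 (percentile 0.01), the 10 MHC class II presentation genes -0.19 (percentile 7.88), the 22 senescence and secretory genes -0.14 (percentile 7.04) and the 20 oxidative phosphorylation genes 0.46 (percentile 96.2). The handling genes moved as well, since the 20 dissociation and immediate early genes had a median of -0.76 (percentile 0.01), with Jun at -2.69 and Atf3 at -2.21. The 12 stromal free RNA genes had a median of -6.53, the 7 adipocyte ones -3.21 and the 4 haemoglobin genes -6.45.

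**Figure D4:**
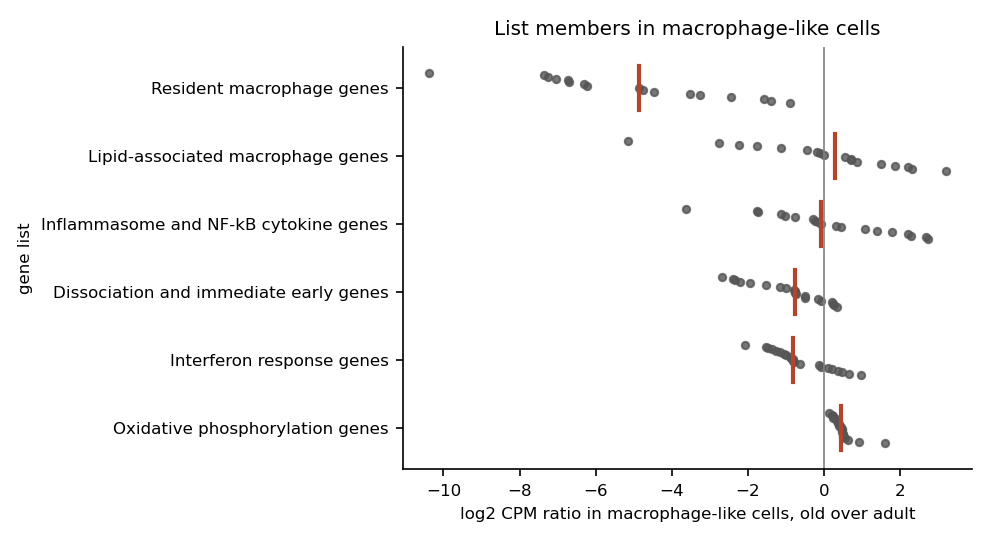
Each point is the log2 ratio of CPM in macrophage-like cells, old over adult, of a measured member of 6 gene lists, and the red line is the list's median. The resident macrophage genes lie at or below -0.90 with a median of -4.85, and the dissociation genes have a median of -0.76.

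The largest single ratios in macrophage-like cells belonged to adult-high genes. The chemokine Ccl8 had 6353 UMIs in adult and 0 in old cells, 1965-fold lower with 3 counts as the floor. The lectin genes Cd209g and Cd209b had 1771 and 707 UMIs and Pla2g2d had 641, each against 0. Cd209f had 4308 UMIs in adult and 1 in old cells. Fcna, at -8.95 (-10.40 to -7.82), and Gas6, at -7.25 (-8.38 to -6.32), followed. Saa3 had 734 UMIs in adult cells, 273 of them in a single cell. Higher in old cells were Olr1, a receptor for oxidised lipoprotein, at 5.18 (3.59 to 7.48), the elastase gene Mmp12 at 5.20 (4.06 to 6.67) with 52 of 205 UMIs in a single cell, and the fractalkine receptor Cx3cr1 at 3.40 (2.88 to 3.96). Etohi1, Sorl1, Sirpb1c, AI504432, Ankrd37, Clec4e and Galnt6 lay between 3.36 and 4.20.

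By list medians, T-cell-like cells had more effector and memory transcripts in old and more naive transcripts in adult. The 17 effector and memory genes had a median of 0.85 (0.64 to 1.09), at percentile 100 of the random lists, and 6 were over 2 times higher in old. Tox, a factor of chronically stimulated T cells, was at 1.69 (0.90 to 2.62), the memory marker Cd44 at 1.29 (0.64 to 2.02) and Ifng, which encodes interferon gamma, at 1.09 (0.25 to 2.07). The 11 naive genes had a median of -0.57 (percentile 0.125), with the lymph node homing receptor Ccr7 at -2.09 (-2.47 to -1.70) and Klf2 at -1.09 (-1.28 to -0.89). Of these 11, 4 were over 2 times higher in adult, and 3 were higher in old. The class was made up of 4 old and 2 adult clusters, and Cd8b1 was among the 10 leading genes of 3 of the old and both of the adult ones. Old cluster L7, with 84 cells, had the naive genes Lef1 and Tcf7 among its leading genes. Ccl5 and Nkg7 were among those of both adult clusters and of old clusters L3 and L4. The 14 VAT regulatory T cell genes had a median of 0.64 (percentile 99.8), but 13 of them stood below 25% of the highest class of the library in which they were higher, and the median was -0.11 at Leiden resolution 0.5, where the adult class took in the ILC2-led cluster of 63 cells, and -0.04 with both libraries clustered together. The 15 inhibitory receptor and exhaustion genes had a median of -0.18, the 17 senescence genes -0.22, the 18 interferon response genes -0.49 and the 20 oxidative phosphorylation genes 0.04.

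Foxp3, the transcription factor of regulatory T cells, was found in the old T cell classes and not in the adult ones. It had 164 UMIs in the old classes, 57.8 CPM (49.3 to 67.4), and 0 in the adult classes, which allows up to 8.73 CPM. Of the 164, 145 were in the Treg-like cluster, which had no adult cluster of its name, and 18 in T-cell-like cells. Only 2.05% of old T-cell-like cells had a Foxp3 UMI, against 3.28% of old macrophage-like cells, so the difference lay in the Treg-like cluster. A UMI was found in 38.1% of old Treg-like cells at a median depth of 1975, against 0.791% of B-cell-like cells at 2653. Those Treg-like cells had Areg at 3951 CPM, Gata3 at 885 and Il10, an anti-inflammatory cytokine, at 598. Foxp3 (ENSMUSG00000039521) lies on chromosome X, from 7573644 to 7595245. The T-cell-like genes with the largest ratios were Nfatc1, Nbeal2, Atp2a3, Yme1l1 and Rbl2, with 125 to 166 UMIs in old and 1 to 3 in adult, and on the adult side Ecm1 at -4.17 (-5.22 to -3.20), Hist1h2ap at -2.94 (-3.61 to -2.27), with 21 of its 41 adult UMIs in a single cell and a ratio of 0.56 with both libraries clustered together, the heat shock gene Dnajb1 at -2.14, Ccr7 and Stmn1 at -2.01. Hist1h2ap and Stmn1 are cell cycle genes, and cycling cells formed a class of their own in the old library alone. In the same cells the 19 dissociation genes had a median of -0.76, the 12 stromal free RNA genes -6.47, the 10 macrophage ones -2.43 and the 3 adipocyte and 3 haemoglobin ones -1.13 and -6.33.

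B-cell-like cells differed little in their subset genes. The 16 age-associated and B1 genes had a median of 0.02 (percentile 78.0) and the 10 follicular genes -0.07 (percentile 66.3), although Bhlhe41, a factor of B1 cells, was at 1.05 (0.25 to 1.95) and Ccr7 at -1.54 (-2.06 to -1.02). The 10 MHC class II genes had a median of -0.35, the 12 interferon response genes -0.51, the 13 senescence genes -0.09 and the 20 oxidative phosphorylation genes -0.04. The 18 dissociation genes had a median of -1.05 (percentile 0), and the largest adult-high ratio was that of one of them, Atf3, at -3.33 (-3.83 to -2.85). Ifitm3 at -2.64, Ifitm2 at -2.33, Map1lc3a at -2.23 and Litaf at -2.18 followed. Ssb was highest in old at 2.33 (0.93 to 4.23), and Lmbrd1, Tmod3, Pum2 and Caprin1 had 71 to 75 UMIs in old and 2 or 3 in adult. The 11 stromal free RNA genes had a median of -6.12 and the 10 macrophage ones -2.20.

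NK- or ILC1-like cells numbered 170 in old and 36 in adult, and the median over all 4519 measured genes was -0.68. The adult sum was small, so the floor of 3 counts stood at 73.3 CPM there. This lowers the ratios of genes with under 3 adult UMIs. The 14 cytotoxic genes had a median of -0.02 (percentile 89.9), with the granzyme gene Gzma at -0.60 (-0.89 to -0.30) and Nkg7 at 0.45 (0.17 to 0.75). The 9 interferon response genes stood at -1.49 (percentile 0.075), with Ifi27l2a at -2.23 (-3.06 to -1.35), and the 17 dissociation genes at -0.96 (percentile 0). The 10 inhibitory genes had a median of -0.29 (percentile 52.65), the 12 senescence genes -0.51 (percentile 23.4) and the 20 oxidative phosphorylation genes 0.05 (percentile 78.3). The 4 stromal free RNA genes stood at -6.07 and the 9 macrophage ones at -2.55. Ccr2 at 2.08 (0.70 to 3.98), Myeov2 at 1.83 (0.44 to 3.72), Ltb, Rap1a and Luc7l2 led in old. These genes had 91 to 159 UMIs in old and only 2 to 4 in adult. Ifitm2 at -2.41, Ly6a at -2.03, Kdm6b at -1.60, Klf2 at -1.58 and Gnb1 at -1.26 led in adult.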

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

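The tests of this part were chosen after the results were seen, except those for free RNA and for resident macrophages in another old cluster. Sex-linked genes, which were kept out of the named genes and serve in the report only for the sex of the animals, gave a signal above the limit that a count of 0 allows. The adult library held 18693 UMIs of Xist, expressed from the inactive X chromosome of females, and the old library 3. The old library held 947 UMIs of the Y-linked gene Ddx3y and 508 of Eif2s3y, and the adult library 0 of each. The libraries thus came from animals of different sex, which the labels used here do not state, and sex changes along with age and sort.

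ILC2 effector genes were lower in old ILC2-like cells by their median, though 5 of the 13 were higher in old. More T cells in the old ILC2-like cluster are argued against by the summed CD3 CPM, which was lower in old ILC2-like cells, at a log2 ratio of -0.77 (-1.11 to -0.42). Free RNA of other adult cells was tested with the 8 effector genes higher in adult. Their median log2 ratio was 4.58 (4.20 to 4.93) in adult ILC2-like over adult T-cell-like cells. This cannot decide, since Il5, Il13, Areg and Arg1 were naming markers of ILC2 and Ccl1 and Furin leading genes of the adult cluster. Of the others, Calca stood at 4.58 and Cxcl2 at 2.29. Effector transcripts of CD3-positive cells in the adult ILC2-like cluster stay open, since the median in cells with no CD3 UMI was -0.44 (-1.10 to 0.40) over 9 genes. Age, sex or sort of the libraries cannot be told apart with 1 library per group.

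Foxp3 was found in the old T cell classes, mainly in the Treg-like cluster, and not in the adult ones. Too few adult T cell UMIs are argued against for the T cell classes together, since 19.9 UMIs (16.9 to 23.2) were expected at the old rate and 0 were seen. That rate rests on the Treg-like cluster, which held 145 of the 164 old UMIs and had no adult cluster of its name. For the T-cell-like class alone, with 18 old UMIs, the question stays open. Age, sex or sort of the libraries cannot be told apart with 1 library per group.

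Resident macrophage genes were lower in old macrophage-like cells. That another old cluster was made up mostly of resident macrophages is argued against. The highest median of these genes in any other old cluster over adult macrophage-like cells was -4.76 (-4.92 to -4.52), in the pDC-like cluster 8. A median over a cluster cannot show a few such cells inside a mixed one. Old immune cells outside the macrophage-like class held 65 UMIs of Timd4, in 44 cells, and 6 of Lyve1. Age, sex or sort of the libraries cannot be told apart with 1 library per group.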

How the results depend on the processing

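The values without the Treg-like cluster, with ILC2-like and Treg-like clusters together, without CD3-positive or mast cells, and in C1q-high macrophages were chosen after seeing the data. Of 71 values under alternatives 52 stayed inside their interval, 18 moved and 1 reversed, and of 281 list medians 231 stayed, 48 moved and 2 reversed. Of 400 ratios of named genes 28 moved, 17 of them with thinned cells, and 1 reversed. Shares were counted 1 library at a time, so these counts leave out that the order of the ILC2-like shares turned at resolution 2, clustered together and in the gate. The Il33 ratio kept its direction in each alternative it was computed under, at 2.40 to 2.66. The adult ILC2-like share was 0% at Leiden resolution 0.5, 1.42% at 2, 0.511% with both libraries clustered together, 0.436% in the gate and 1.31% without CD3. The old share was 2.77% at resolution 2, 2.09% clustered together, 1.11% in the gate and 0.843% without CD3. The 0% rests on a name, since adult cluster L2 of 63 cells at resolution 0.5 scored 3.72 for both T cells and ILC2, was led by Areg and Ccl1, and was named T-cell-like. The macrophage difference was -47.6 points at resolution 2, -50.2 clustered together and -60.3 with 500 genes and 5% mitochondrial UMIs. The T cell difference was 24.6 points at resolution 0.5, 25.6 clustered together and 20.5 without the Treg-like cluster. Clustering together gave an adult immune share of 30.8%, an effector median of -1.33 and a Hist1h2ap ratio of 0.56 in T cells, which reversed. The ILC2-like share of Il1rl1 was 14.8% thinned and 57.5% with Treg-like cells. The lipid-associated macrophage median reversed to -0.20 thinned and was 0.58 in C1q-high clusters. The VAT regulatory T cell median reversed to -0.11 at resolution 0.5 and -0.043 clustered together. At resolution 0.5 the adult T-cell-like class held that cluster, and so was another mix of cells, for this median and for the T cell difference. The cause was not tested. For the same reason of naming the effector median has no value at resolution 0.5. The 85487 adult ILC2-like UMIs limit what can be said of rare cytokines. No paired analysis was possible because each group had 1 library.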

Other observations

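Tslp, an epithelial cytokine that acts on ILC2 and dendritic cells, was carried by adult macrophage-like cells. It stood at 160 CPM (147 to 175) from 510 UMIs, against 42.7 CPM in stromal-progenitor-like cells. A UMI was found in 26.2% of macrophage-like cells at a median depth of 2117 UMIs, against 1.19% of T-cell-like cells at 1312, 7.69% of B-cell-like cells at 1451 and 8.72% of stromal-progenitor-like cells at 2198. Within the class it was at 268 CPM (239 to 300) in cluster 3, 188 in cluster 4 and 14.6 in cluster 5, so it followed the clusters that carried Lyve1. Old macrophage-like cells held 3 UMIs. Tslp (ENSMUSG00000024379) lies on chromosome 18, from 32815383 to 32819797.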
